A study of Mus musculus with 2 samples.

How the data were processed

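Total RNA from the hippocampus of male B6CASTF1/J mice at postnatal day 14 was sequenced in 2 libraries, which the labels number as biological replicates 1 and 2 of a single group. B6CASTF1/J mice are hybrids of C57BL/6J and CAST/EiJ parents. Each label lists 3 males under animal numbers of its own, without saying that their RNA was pooled, 300 ng of starting RNA, and ERCC spike-ins (synthetic RNAs of known sequence) for stranded libraries with reduced ribosomal RNA. With 1 group there was no comparison between conditions. Levels within the tissue, ratios between genes and differences between the replicates were described instead.

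Gene values were expected counts deposited by the authors, which are estimated reads per gene without normalisation. Per the file headers, the same gene tables give transcripts scaled to a fixed total per library (TPM), a posterior mean count and a posterior standard deviation of the count. That deposited standard deviation measures how uncertainly reads were assigned to a gene. TPM values deposited by the authors sum over all entries of a table, spike-ins included. Transcript values came from a pair of tables per library. The columns of the first are in the layout of RSEM and those of the second in the layout of kallisto, per the file headers. The first transcript table also gives, per the file headers, the percent of a gene's TPM in each transcript. The second gives estimated counts and TPM, as deposited. The build is mm10 and the annotation GENCODE M21, per the labels and the notes deposited with the tables. The aligner, the quantifiers' settings and their versions are not given in the sources used here.

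The gene tables held 81881 entries. Of these, 55536 were genes, all matched to GENCODE M21, 97 were spike-ins, and 26248 carried only a number and named no gene. With totals rounded to whole counts, the numbered entries held 2.73e-05% of the counts of replicate 1 and 9.4e-06% of those of replicate 2, and they and the spike-ins were left out of gene totals. Expected counts summed to 29296141 in replicate 1 and 31910050 in replicate 2. The kallisto-format counts summed to 29826541 and 32236502. A count of 0 allows up to 3 counts, or 0.103 and 0.0945 CPM (counts scaled to the library) in replicates 1 and 2. Shares of counts in a single library have exact Clopper-Pearson 95% intervals. Intervals and limits cover counting error only, since reads are not independent molecules.

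Genes were called detected at a TPM of at least 1 in both libraries. Correlations were taken across genes on log2(TPM + 1), with a mean TPM of at least 1. For differences between replicates, expected counts were rounded to whole numbers for the test, and library sizes were scaled by the trimmed mean of M-values (TMM). The log2 ratio of replicate 2 to replicate 1 had a prior count of 0.5, and genes needed a mean count of at least 10. Each gene was tested with an exact two-sided binomial test on its counts in the 2 libraries, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Adjusted p-values in the text come from that test. It compares these libraries beyond counting noise and does not compare conditions. The biological coefficient of variation was the square root of edgeR's common dispersion (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with an intercept as the sole term. Other values were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

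Gene lists for 24 cell types and 20 pathways, 20 gene pairs and 20 genes for transcript shares were fixed before the data were examined, as were the tests, thresholds and all alternatives not said to be chosen later. Of the 349 list genes, 348 were in the tables. Each list's level is the median over its members of the mean TPM. The SD beside a level is that of the 2 library medians, so a level can lie outside both. Each list's replicate difference is the median log2 ratio of members with a mean count of at least 10, in lists with at least 3 such members. It is given as a percentile among 10000 random lists of the same size, matched on mean count in 20 bins, as a description of these libraries. Genes are not replicates, so no p-value was computed across them. A pair was called different when both libraries gave the same sign and the mean log2 ratio of TPM exceeded 0.5 and 2 SD. An exact sign-flip test over 2 libraries cannot go below a two-sided p of 0.5, so none was run.

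By the rule fixed in advance, the text names from each list some of the up to 4 members with the highest mean TPM and any member under a mean TPM of 1. It also names genes of the pairs and of the transcript list, the 10 genes with the highest mean TPM apart from mitochondrial genes, all sex-linked genes of the list, and the 10 genes with the largest log2 ratio in each direction among those past the test with a mean count of at least 50. Other genes are said to be chosen after their values were seen. List members named beyond that rule for their replicate difference were likewise chosen after their values were seen.

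The counting test was tested on simulated data with counting noise only. Counts were drawn for the 18322 genes tested with a seeded set of changed genes. The test called 49 of 67 genes changed 1.5-fold, 48 of 67 changed 2-fold and 64 of 66 changed 4-fold. Among 18122 unchanged genes it called 10. The test assumes that noise, so its error rate under a wider spread between libraries was not measured. Of simulated lists with no shift, 5% fell outside the central 95% of random lists, and of lists shifted by 0.3 (log2), 99% did. The noise of their members was independent in that simulation and came from counting only. Unchanged genes there had a median absolute log2 ratio of 0.07, against 0.142 for genes in the real libraries. The 99% is thus not the sensitivity of the list comparison in these libraries. Simulated coefficients of variation of 0.05, 0.1 and 0.2 were estimated as 0.0508, 0.0994 and 0.198.

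The alternatives were other scalings (median-ratio size factors as in DESeq2, total count, spike-in total), other count and TPM minimums, other pseudocounts, posterior mean counts, the kallisto-format table summed to genes, edgeR's exact test with a set spread, random lists without matching, and each library alone. A filter on the posterior standard deviation, at most 5% of the count in both libraries, was chosen after seeing the data.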

Results

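The series measured total RNA of the hippocampus, reported as a layer of hippocampus in the labels, in male B6CASTF1/J mice at postnatal day 14. A single group of 2 biological replicates was sequenced. Each label lists its own 3 males, and whether their RNA was pooled is not given in the sources used here. The gene tables held 29296141 expected counts in replicate 1 and 31910050 in replicate 2. Values are means ± SD over n = 2 unless a library is named, and log2 ratios are replicate 2 over replicate 1. A list level is instead the median over members of the mean TPM, with the SD of the 2 library medians. It can lie outside both medians, as GABA-A receptor genes did at 51.6 with 49.3 and 50.3. No purpose is stated in the sources used here beyond measuring this tissue.

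Mitochondrially encoded genes took 8.04% ± 1.21 of the gene counts (SD, n = 2), most of them from the ribosomal RNAs mt-Rnr2 (chromosome M, 1094 to 2675, mm10) and mt-Rnr1. In replicate 1 their share was 8.895% (Clopper-Pearson 95% interval 8.89 to 8.91), and in replicate 2 it was 7.18% (7.18 to 7.19). Mitochondrial ribosomal RNA alone took 6.38% ± 1.05. Protein-coding genes held 81.6% ± 1.53 of the gene counts and miscellaneous RNAs such as 7SL and 7SK 4.66% ± 0.126. Long intergenic noncoding RNAs held 5.002% ± 0.214. Of their counts, Gm26917 of the ribosomal RNA-related list held 797608 of 1502095 in replicate 1 and 911447 of 1540596 in replicate 2. The 10 genes with most counts took 16.4% ± 1.39 and the 100 genes with most counts 27.8% ± 1.34. Spike-ins made up 0.516% of all counts in replicate 1 (0.514 to 0.519) and 0.484% in replicate 2 (0.482 to 0.487).

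On the TPM scale, with mitochondrial genes kept apart, the short structural RNAs led. The 7SL genes Rn7s1 and Rn7s2 each had a TPM of 141000 ± 2140 (n = 2), with the reads divided equally between them, and Rn7sk (ENSMUSG00000065037.1, chromosome 9, 78175303 to 78175633) had 49150 ± 528. Next came Gm26917, annotated as a lincRNA and a member of the ribosomal RNA-related list, at 15220 ± 927, and the RNase P RNA Rpph1 at 8861 ± 413. Malat1 (ENSMUSG00000092341.3, chromosome 19, 5795690 to 5802672) had 4231 ± 894 and Rmrp 3260 ± 310. The other members of the first 10 were the unprocessed pseudogenes Gm28661 at 7005 ± 453, Gm10925 at 5795 ± 498 and Gm28437 at 4205 ± 484. They lie together on chromosome 1 between 24613189 and 24615565 and were added to the named genes after their values were seen. Their posterior standard deviation reached 3.7%, 5.3% and 7.4% of the count, so their reads were shared with other entries. Which entries these were was not examined, and mitochondrial genes were not excluded. These TPM values thus need not come from transcription on chromosome 1. Any mitochondrial reads among them would be missing from the mitochondrial share given above. In replicate 1 they had 86039, 71823 and 62769 counts, against 61937, 14174 and 35118 in the kallisto-format table. Rn7s1, Rn7s2, Rn7sk, Rpph1 and the mitochondrial ribosomal RNAs together took 42.6% of the TPM of replicate 1 and 40.5% of that of replicate 2, which lowers the TPM of every other gene in these tables.

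At a TPM of at least 1, 14865 genes were detected in both libraries, 12924 of them protein-coding. There were 15636 in replicate 1, 15329 in replicate 2 and 16100 in either, so 92.3% of those in either library were in both. At a TPM of at least 5, 10631 genes were detected in both, and at 100, 913. The label male was checked with the sex-linked list. Ddx3y (ENSMUSG00000069045.11, chromosome Y, 1260771 to 1286629) had a TPM of 21.1 ± 0.141, Eif2s3y 31.8 ± 1.04, Uty 10.6 ± 0.905 and Kdm5d 8.46 ± 0.283. Xist had a TPM of 0.035 ± 0.0212, and Tsix 0.395 ± 0.0636. The ratio of Ddx3y to Xist was 9.38 ± 0.93 on the log2 scale.

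Excitatory neuron genes were the most abundant cell type list, with a median TPM of 384 ± 11 (n = 2). Camk2a (ENSMUSG00000024617.16, chromosome 18, 60925618 to 60988152) had 1283 ± 33.2, Nrgn 741 ± 94.3, Slc17a7 675 ± 16.9 and Neurod6 93.1 ± 5.52. Among the regional lists, the medians were 39.3 ± 3.7 for CA1 (Mpped1 67.4, Wfs1 56.1, Fibcd1 52.2, Gpr161 26.4), 20.1 ± 0.95 for CA3 (Bok 33.9, Nectin3 31.1, Grik4 27.1, Npy2r 13.2), 10.8 ± 1.8 for dentate granule neurons (Prox1 53.4, Stxbp6 23.7, C1ql2 21.7, Lct 16.8) and 9.8 ± 0.78 for CA2 (Pcp4 147, Rgs14 26.1, Cacng5 9.805, Amigo2 8.425). The CA2 gene Map3k15 stayed under a TPM of 1, at 0.495 ± 0.106. Inhibitory interneurons had a median of 32.2 ± 0.42, led by Sst at 171 ± 46.1 and Gad1 at 114 ± 14.1, with Npy at 42.6 ± 14.5 and Gad2 at 35.0 ± 2.24. Of the Cajal-Retzius list, Reln had 39.9 ± 4.96 and Trp73 1.68 ± 0.141, while Ebf3, Lhx1 and Lhx5 were under 1.

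Astrocyte genes had a median TPM of 127 ± 20 (n = 2), with Slc1a2 at 1033 ± 7.94, Aldoc at 307 ± 14.7, Slc1a3 at 215 ± 19.1 and Gja1 at 137 ± 2.67. Myelinating oligodendrocyte genes had 82.6 ± 36.0, with Mbp at 626 ± 264, Cnp at 126 ± 32.5 and Mobp at 116 ± 54.3. The earlier stages of the lineage were lower, at 12.4 ± 2.8 for newly formed oligodendrocytes (Bcas1 46.1, Gpr17 45.7, Itpr2 13.3, 9630013A20Rik 11.6) and 16.1 ± 1.3 for precursors (Pdgfra 35.9, C1ql1 17.2, Cspg4 15.0, Lhfpl3 11.7). Microglia had a median of 18.2 ± 0.88 (Csf1r 36.3, P2ry12 33.6, C1qb 19.7), endothelial cells 13.9 ± 1.8 (Cldn5 34.05, Ly6c1 23.3, Itm2a 23.2, Slco1a4 16.1), mural cells 8.28 ± 1.0 (Rgs5 44.9, Vtn 27.9) and fibroblasts 13.2 ± 0.21 (Dcn 20.6, Col1a1 16.0). Red blood cell genes had 175 ± 25, from Hbb-bs at 238 ± 50.7 and Hba-a1 at 200.5 ± 37.3, of which the alpha-globin copies share reads.

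Immature neuron genes had a median TPM of 20.5 ± 7.0 (n = 2), with Dcx (chromosome X, 143855842 to 143933311) at 33.1 ± 7.71, Sox4 at 23.9 ± 5.42, Neurod1 at 23.7 ± 4.74 and Igfbpl1 at 20.5 ± 6.95. Stem and radial glia-like genes had 7.85 ± 1.1 (Hopx 33.6, Sox2 22.6, Emx2 10.9, Pax6 4.755) and proliferating cells 1.69 ± 0.46 (Top2a 4.29, Rrm2 2.985, Mki67 1.85, Ccnb1 1.79). Thalamic neurons had 3.42 ± 0.73, with Prkcd at 20.2 ± 4.5 and Tcf7l2 at 12.7 ± 7.69, and Gbx2 under 1 with 2 and 0 counts. Striatal projection neurons had 3.83 ± 0.36 (Ppp1r1b 13.5, Penk 9.55) and neocortical neurons 11.7 ± 0.59 (Tle4 17.1, Fezf2 16.1, Foxp2 0.955). Choroid plexus genes had 0.69 ± 0.57, where Ttr at 65.8 ± 28.3 stood apart and Otx2, Clic6, Aqp1 and Kcnj13 were under 1. Ependymal genes had 1.49 ± 0.54, with Foxj1 at 3.10 ± 0.29 and Tmem212 under 1.

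**Figure D1:**
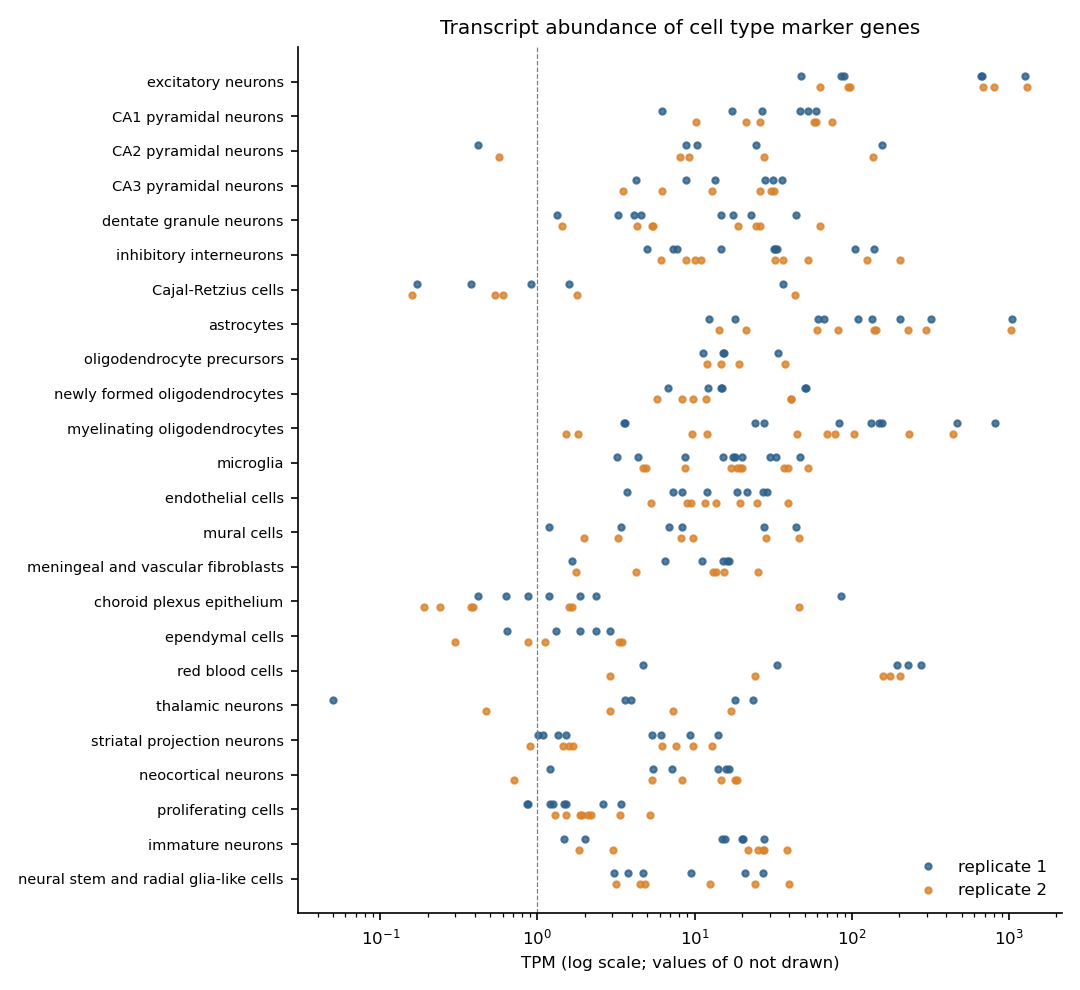
TPM of each marker gene in the 24 cell type lists (log axis), with replicate 1 in blue and replicate 2 in orange; the dashed line marks a TPM of 1. Excitatory neuron and astrocyte genes reach the highest values, and myelinating oligodendrocyte genes lie lower in replicate 2 than in replicate 1.

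Glutamate receptor subunits were led by AMPA receptor genes, with a median TPM of 152 ± 4.1 (n = 2), where Gria1 had 259 ± 11 and Gria2 248 ± 8.01, Gria3 56.8 ± 1.68 and Gria4 25.2 ± 0.926. NMDA receptor genes had a median of 24.1 ± 5.8, with Grin1 at 190 ± 0.764, Grin2b at 161 ± 0.262 and Grin2a at 127.5 ± 0.813, and Grin3b under 1. Kainate receptor genes had 27.1 ± 1.4 (Grik5 115, Grik2 42.0) and metabotropic receptors 20.7 ± 2.1 (Grm5 102, Grm3 34.2), with Grm6 under 1. GABA-A receptor genes had 51.6 ± 0.69, with Gabra5 at 94.8 ± 6.96, and Gabra6 at 2 counts in each library. Of the glycine receptor genes, Glrb had 56.4 ± 0.863 and Glra2 8.595 ± 2.34, while Glra1, Glra3 and Glra4 were under 1. The presynaptic list had 154 ± 4.7 (Syp 792, Snap25 629, Vamp2 472, Syt1 376), the postsynaptic scaffolds 92.9 ± 16.0 (Dlg4 393, Shank1 251, Dlgap1 174), and the sodium, HCN and KCNQ channels 29.8 ± 4.5 (Scn2a 121, Scn8a 92.8).

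Imprinted genes had a median TPM of 31.3 ± 1.1 (n = 2), with Meg3 at 1382 ± 211, Gnas at 824 ± 29.2, Rian at 637 ± 28.8 and Nnat at 523 ± 27.5. Cholesterol synthesis genes had 32.0 ± 5.2 (Hmgcs1 193), extracellular matrix genes 26.4 ± 4.5 (Bcan 194, Ncan 181), and immediate early genes 8.76 ± 2.0 (Egr1 35.5, Egr3 33.4, Arc 26.3, Junb 22.2). Heat shock genes had 4.75 ± 1.0, where Hsp90aa1 reached 406 ± 18.0 and Atf3 was under 1. Interferon-stimulated genes had 0.29 ± 0.0071, with Ifit1, Ifit3, Isg15, Irf7, Usp18 and Oasl2 under a TPM of 1. Mitochondrially encoded mRNAs had 2040 ± 200 (mt-Co1 5588, mt-Cytb 3339, mt-Nd1 3010), nuclear long noncoding RNAs 210 ± 49.0 (Malat1 4231, Snhg14 612, Snhg11 210), ribosomal RNA-related genes 30900 ± 5200 and structural noncoding RNAs 1650 ± 160. Rny3 had 0 counts in both libraries, which allows up to 0.103 and 0.0945 CPM (counts scaled to the library).

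Of the 20 gene pairs, 14 differed by the rule set in advance. The chloride transporter genes Slc12a5 and Slc12a2 differed by 3.27 ± 0.16 on the log2 scale, with Slc12a5 higher by 9.64-fold. Dlg4 lay above Dlg3 by 2.69 ± 0.02, Bcan above Vcan by 3.58 ± 0.095 and Slc17a7 above Slc17a6 by 5.68 ± 0.02. Other log2 ratios were 3.72 ± 0.68 for Sst to Pvalb, 1.70 ± 0.086 for Gad1 to Gad2, 1.53 ± 0.051 for Camk2a to Camk2b and 3.06 ± 0.019 for Hbb-bs to Hbb-bt. The pairs not called were Grin2b to Grin2a at 0.34 ± 0.012, Scn2a to Scn8a at 0.39 ± 0.13, Scn1a to Scn3a at 0.20 ± 0.37, Gria2 to Gria1 at -0.07 ± 0.11, Syn1 to Syn2 at -0.23 ± 0.0036 and Hba-a1 to Hba-a2 at 0.19 ± 0.064. In the kallisto-format table Hba-a1 to Hba-a2 was 1.91 ± 0.2 and called.

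Of the 20 genes chosen for transcript shares, 11 had a transcript that held over 50% of the gene's TPM. App-201 held 92.1% ± 0.29 (SD, n = 2), Snap25-201 80.5% ± 3.4, Mapt-204 73.5% ± 4.5, Gria1-201 72.6% ± 1.9 and Camk2a-203 64.8% ± 0.83. Gria3-201, Mbp-211, Cdc42-201, Gria2-202 and Dlg4-203 held between 54.6% and 59.0%. Low shares were those of Ank3 (Ank3-244, 21% ± 1.3, of 47 transcripts) and Homer1 (Homer1-203, 29.6% ± 0.15). Between these lay Ntrk2-202 at 34.9%, Gria4-203 and Grin1-201 at 38.4%, Map2-204 at 42.3%, Bdnf-205 at 49.5% and the leading Tpm1 transcript at 49.5%. The leading transcript was the same in both replicates in 19 genes, Homer1 being the exception, and the same in both tables in 17. In the kallisto-format table Mbp-201 led Mbp with 26.2% ± 0.24 and Mbp-211 held 17.1% ± 3.3, and Dlg4-206 and Homer1-207 led their genes with 28.2% ± 0.6 and 26.1% ± 3.5.

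The replicates correlated across 15499 genes with a Pearson r of 0.982 and a Spearman rho of 0.984, where genes are not independent replicates. Over the 18322 genes tested, the median absolute log2 ratio was 0.14, or 1.10-fold. Of these, 4078 genes (22.3%) differed beyond counting noise by the exact binomial test, 2259 higher in replicate 2 and 1819 higher in replicate 1, and 5841 had an unadjusted p under 0.05. Scaling to the ERCC spike-in total moved the median log2 ratio of all genes from 0.00 to 0.11 and the split of genes differing between replicates from 55.4% to 85.1% higher in replicate 2. With edgeR's exact test at a coefficient of variation of 0.1, the genes differing between replicates fell to 173 and the majority turned, with 53 higher in replicate 2 and 120 higher in replicate 1. At the spread of the spike-ins there were 1223, with 527 and 696. At least 2-fold differences past the test were seen in 320 genes, 87 higher in replicate 2 and 233 higher in replicate 1, and with spike-in scaling 132 and 185. The genes differing over 2-fold between replicates were 97 at a mean count of at least 50 and 137 with edgeR at 0.1. They were 209 with a posterior standard deviation of at most 5% of the count (27 higher in replicate 2, 182 in replicate 1), a filter chosen after seeing the data. Of the 320, 111 had a posterior standard deviation over 5% of the count, so their reads were shared with other genes, and 80 were of the classes TEC (an annotation class of unproven transcripts) or sense intronic. The biological coefficient of variation was 0.1004. For the 32 spike-ins with a mean count of at least 50 the SD of the log2 ratio was 0.15. Counting alone gives 0.14 there, and genes of like count had 0.23. For the 15 with a mean count of at least 500 it was 0.084, where counting alone gives 0.043 and genes of like count had 0.14. At high counts the spike-ins thus spread beyond counting noise as well.

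**Figure D2:**
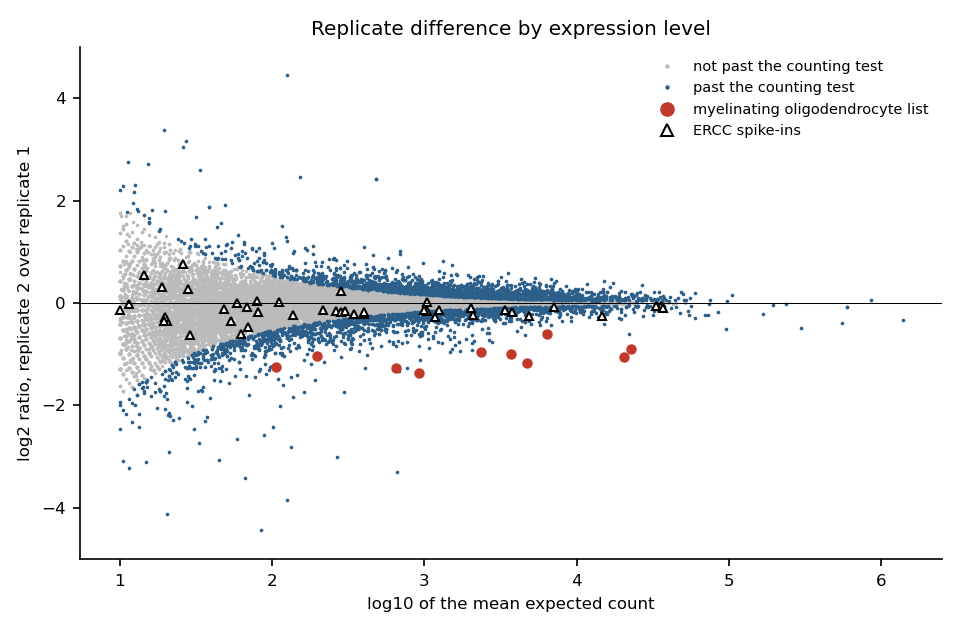
Log2 ratio of replicate 2 over replicate 1 against the log10 mean expected count for each gene with a mean count of at least 10; blue genes passed the counting test, red circles are the myelinating oligodendrocyte list and open triangles are ERCC spike-ins. The 30 genes beyond a log2 ratio of 5 in size are not drawn, and all 10 genes of the myelin list lie below 0.

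The largest ratios belonged mostly to genes with uncertain read assignment. Of the 10 genes highest in replicate 1 by ratio, Gm14760, Hist1h2ah, Gm14288, Gm10163, Fam220a and Rps12l1 had a posterior standard deviation over 5% of the count in at least 1 library, and in the kallisto-format table the ratios of Hist1h2ah and Fam220a turned positive. The other 4 were Plin4 (ENSMUSG00000002831.13, chromosome 17, 56100591 to 56109803; log2 ratio -3.42, adjusted p 3.2e-24), with 121 and 12 counts, Wnt9b (-2.66), Gm43398 (-2.58) and Sult1a1 (-2.42). All 10 genes highest in replicate 2 were uncertain in this sense: Gm24497, Gm20388, Gm45837, Gm5559, Myl12b (ENSMUSG00000117098.1), Hist1h2ai, Gm10240, Gm13370, Gm28539 and Gm5776. Among protein-coding genes with well-assigned reads, chosen after the values were seen, the next highest in replicate 1 were Smyd1 (-1.79), Grid2ip (-1.73), Synpo2 (-1.73), Map3k6 (-1.61), Fzd10 (-1.56), Pla2g3 (-1.50) and Fign (-1.49). Highest in replicate 2 in the same way were Dio3 (chromosome 12, 110279068 to 110281097; 1.2, adjusted p 0.00052), Hist1h1b (1.18), Rbp4 (1.08), Cdt1 (1.08), Prokr2 (1.03), Cyp26b1 (1.01, adjusted p 1.7e-33), Eps8l1 (1.01), P2ry6 (0.97), Anxa4 (0.96) and Sox3 (0.93).

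Myelinating oligodendrocyte genes were lower in replicate 2, with a median log2 ratio of -1.05, or 2.07-fold, and all 10 members past the test, over all genes and adjusted over the list alone. Mbp (ENSMUSG00000041607.17, chromosome 18, 82475146 to 82585637) had a TPM of 813 and 439 (log2 ratio -0.90, counting interval -0.92 to -0.87) and Mobp (ENSMUSG00000032517.16, chromosome 9, 120149707 to 120181484) a log2 ratio of -1.18. Mal (-1.37), Mog (-1.27) and Opalin (-1.24) had the largest ratios and Cnp the smallest (-0.60). The list's median lay below all 10000 random lists, whose central 95% ran from -0.07 to 0.12. Newly formed oligodendrocytes had a median of -0.35 with 5 of 6 members lower in replicate 2, from 9630013A20Rik (-0.74) to Itpr2 (-0.22), and Nkx2-2 (-0.26) not past the test. The precursor list had a median of 0.04, inside its random range of -0.12 to 0.18, with C1ql1 (0.30) past the test and Pdgfra, Cspg4 and Lhfpl3 not. With 1 library on each side these ratios describe the libraries and carry no replicate error.

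Thalamic, choroid plexus, red blood cell and nuclear noncoding RNA lists were lower in replicate 2 as well. The thalamic list had a median log2 ratio of -0.89 with all 4 tested members past the test (also adjusted over the list alone): Tcf7l2 (ENSMUSG00000024985.19, chromosome 19, 55741820 to 55933654) had a TPM of 18.2 and 7.30 (-1.33, adjusted p 1.5e-57), Tnnt1 had 57 and 9 counts (-2.73), Lef1 -0.45 and Prkcd -0.43. The choroid plexus list had -0.84, where Ttr had a TPM of 85.9 and 45.8 and Otx2 32 and 8 counts (-2.07), with 4 of 6 members past the test. All 5 red blood cell genes were lower, with a median of -0.51, Hbb-bs at -0.48 and Alas2 at -0.88. All 5 nuclear long noncoding RNAs were lower, with a median of -0.49, led by Neat1 (-0.91), Snhg11 (-0.60) and Malat1 (-0.49), with Miat at -0.27 and Snhg14 at -0.26. Mitochondrially encoded mRNAs had a median of -0.23 with 11 of 13 lower, mt-Co3 higher (0.11) and mt-Nd6 not past the test, while the lower ratio of mt-Co2 (-0.70) reversed to 0.26 in the kallisto-format table. The ribosomal RNA-related list had -0.34, from mt-Rnr1 (-0.39) and mt-Rnr2 (-0.34) against Gm26917 (0.05).

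Smaller negative medians outside the random range were those of CA3 (-0.18, 4 of 6 past the test and 6 adjusted over the list alone, Cdh24 at -0.53), CA2 (-0.19, Pcp4 at -0.24 and Cacng5 at -0.21) and immediate early genes (-0.13, with Fosb -0.65, Fos -0.60, Npas4 -0.47 and Arc -0.31 lower and Egr3 0.26 higher). The AMPA receptor list had -0.10 and the imprinted list -0.06, and both medians turned positive with spike-in scaling, at 0.01 and 0.04. By library median TPM the imprinted list was higher in replicate 2 (30.5 and 32.1). Against random lists not matched on expression, the CA2, CA3, immediate early, AMPA receptor, imprinted and ribosomal RNA-related lists came to lie inside the range, as did the CA2, AMPA receptor and imprinted lists in the kallisto-format table. Within the imprinted list Kcnq1ot1 (-0.62), Plagl1 (-0.62) and Meg3 (-0.51) were lower in replicate 2 and Peg10 (0.67) was higher.

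Lists higher in replicate 2 were led by dividing and immature cells. Proliferating cells had a median log2 ratio of 0.46, with Cenpf (0.72), Mki67 (0.47) and Top2a (0.44) past the test and 5 of 8 members not, and the same 3 were past it adjusted over the list alone. Immature neurons had 0.42 with 6 of 7 members past the test in both adjustments, from Igfbpl1 (0.78, TPM 15.6 and 25.4, adjusted p 5.1e-29) and Draxin (0.54) to Neurod1 (0.36), and Eomes (0.37) not. Dentate granule neurons had 0.34 with 5 of 8 past the test, led by Dsp (0.60), C1ql2 (0.52) and Prox1 (ENSMUSG00000010175.13, chromosome 1, 190118035 to 190170714; 0.44, TPM 43.9 and 63.0). CA1 genes had 0.25, with Mpped1 (0.29), Fibcd1 (0.26), Pou3f1 (0.24) and Wfs1 (0.12) among the members past the test. The Cajal-Retzius list had 0.32, with Reln (0.32) alone past the test, stem and radial glia-like cells 0.19 (Hopx 0.50, Nes 0.36; 2 past the test and 4 adjusted over the list alone) and endothelial cells 0.16 (Tek 0.49, Cldn5 0.41, against Ly6c1 -0.57 and Slco1a4 -0.33). Extracellular matrix genes had 0.14, from Tnc at 0.82 to Hapln4 at -0.79, and cholesterol synthesis genes 0.12, with Fdft1 at 0.23. The last 2 lists came to lie inside the range without matching on expression, and the endothelial list in the kallisto-format table. By library median TPM over all members, the Cajal-Retzius list (0.91 and 0.6) and the endothelial list (15.2 and 12.6) were instead lower in replicate 2. By that measure the other lists of this paragraph were higher in replicate 2.

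In total 22 of 44 lists lay outside the central 95% of their random lists, 9 above and 13 below. Chance would give 2.2 if the members of a list varied independently. Members that vary together would give more, so 2.2 does not measure chance here. The astrocyte list lay inside it with members going both ways, Aqp4 (0.40) and Gfap (0.33) higher and Fgfr3 (-0.24) lower in replicate 2. The interneuron list also lay inside, with Npy (0.66), Sst (0.51) and Lhx6 (0.39) higher and Pvalb (-0.45) lower. Inside it too were excitatory neurons, microglia, mural cells, fibroblasts, ependymal cells, striatal and neocortical neurons, the NMDA, kainate, metabotropic glutamate, GABA-A and glycine receptors, both synaptic lists, the ion channels, heat shock, interferon-stimulated, sex-linked and structural RNA lists. Among these, Foxp2 (-1.25) of the neocortical list was lower and Dcn (0.57) of the fibroblast list higher, with Slc6a20a (-0.66) lower.

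**Figure D3:**
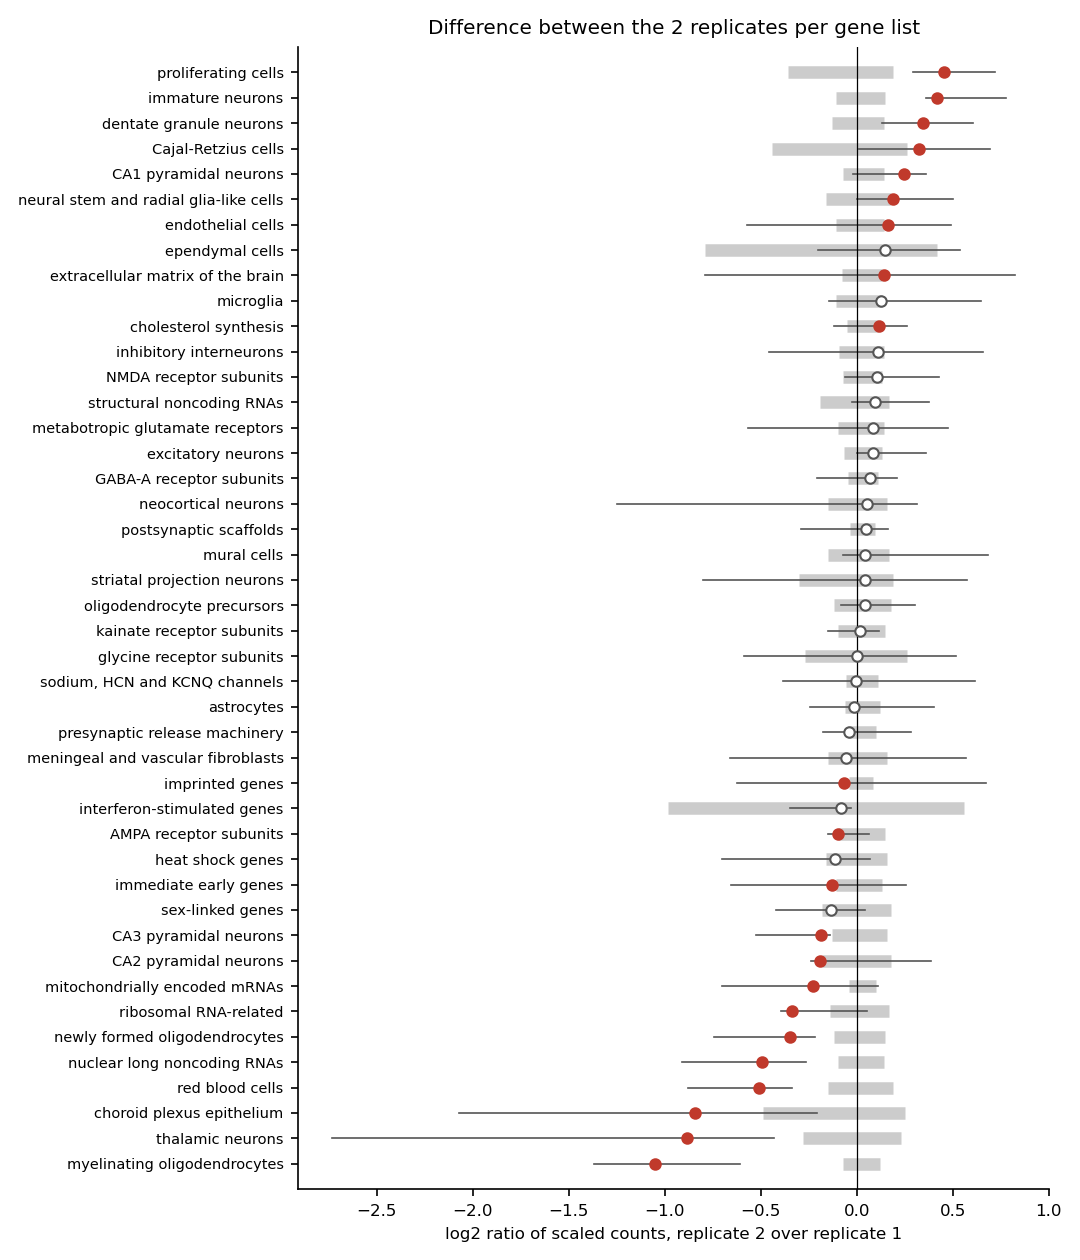
Median log2 ratio of replicate 2 over replicate 1 for each of the 44 lists (circles; filled red where the median lies outside the central 95% of random lists), with thin lines from the lowest to the highest member and grey bars for the central 95% of 10000 matched random lists. Myelinating oligodendrocytes lie lowest at -1.05 and proliferating cells highest at 0.46.

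By gene class, the 1356 TEC genes had a median log2 ratio of -0.48 (quartiles -0.74 and -0.19), with 250 past the test lower in replicate 2 and 3 higher. The 139 sense intronic genes had -0.58, with 27 lower and 0 higher. Long intergenic noncoding RNAs (515 genes) had -0.14, with 55 lower and 13 higher, and the 14684 protein-coding genes 0.02, with 1381 lower and 2123 higher. TEC genes held 0.308% of the gene counts of replicate 1 (Clopper-Pearson 95% interval 0.306 to 0.31) and 0.228% of replicate 2 (0.226 to 0.23).

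The 2 transcript tables of a library were compared across 141767 transcripts on log2(TPM + 1), as a check of how far transcript levels depend on the quantification. Pearson r was 0.793 in both replicates and Spearman rho 0.741 and 0.739. Summed to 55450 genes, r was 0.9503 and 0.954. Among the 57119 and 54750 transcripts with a TPM of at least 1 in either table, r fell to 0.599 and 0.598 and rho to 0.506 and 0.497, and among such genes r was 0.874 and 0.876. The tables parted at short RNAs. Rn7sk had 228346 and 246902 counts in replicates 1 and 2 of the RSEM-format table and 0 in the kallisto-format table, and Rpph1 had 38043 and 43276 against 2 and 2. Over 75 genes with a single transcript under 300 nt, the median ratio of kallisto-format to RSEM-format counts was 0, and over 1326 such genes longer than 2000 nt it was 1.07. As a result protein-coding genes held 46.3% of the RSEM-format TPM of replicate 1 and 76.7% of the kallisto-format TPM.

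**Figure D4:**
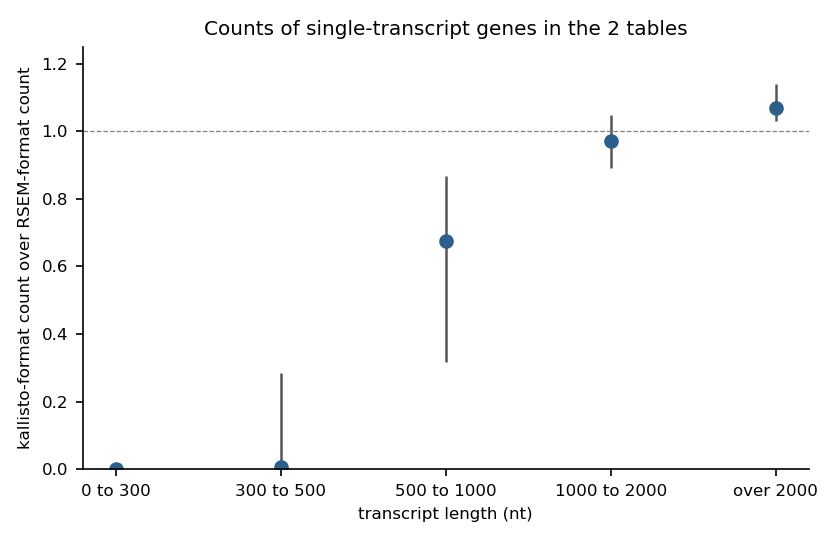
Ratio of kallisto-format to RSEM-format counts in single-transcript genes with a mean count of at least 50, by transcript length in nt; points are medians and lines run from the lower to the upper quartile. The median is 0 under 300 nt and 1.07 over 2000 nt.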

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

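Entries that carry only a number and name no gene lie outside every comparison of the report. They held 7.82 expected counts in replicate 1, above the 3 counts that a count of 0 allows, and 3 counts in replicate 2. Of the 26248 numbered entries, 7 had a read in either library. The phiX174 control sequence had 0 counts in both libraries, which allows up to 0.103 and 0.0945 CPM (counts scaled to the library) in replicates 1 and 2. No explanation was tested for these counts.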

How the results depend on the processing

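The filter on the posterior standard deviation was chosen after seeing the data, and all other alternatives before. The number of genes detected (10631 to 16860), the mitochondrial share of counts, the number of lists at a median TPM of at least 1 (40 or 41), of pairs called (14) and of genes with a transcript over 50% (9 to 12) stayed within 1.5 times or within 1 SD of the values reported under every alternative run. Leaving out each library in turn gave 15329 and 15636 genes detected. Levels of single lists moved by more than 1 SD in 69 values and stayed in 107, shares of single leading transcripts moved in 16 and stayed in 44, and shares of counts other than the mitochondrial moved in 3 and stayed in 3.

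The 4078 genes differing between replicates became 6410 with spike-in scaling (5456 higher in replicate 2, 954 higher in replicate 1). They became 1223 with edgeR's exact test at the spread of the spike-ins (527 and 696) and 173 at a coefficient of variation of 0.1 (53 and 120). The 320 genes differing over 2-fold between replicates became 97 with a mean count of at least 50, 209 with a posterior SD at most 5% of the count and 137 with edgeR at 0.1. Stricter filters tested fewer genes and edgeR's test allows more spread, by construction. With DESeq2 size factors 62.8% of the genes past the test were higher in replicate 2, with total count 61.3% and with spike-in scaling 85.1%, against 55.4% with TMM. The posterior filter changed the split of 2-fold genes to 27 higher in replicate 2 and 182 higher in replicate 1.

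The median absolute log2 ratio of 0.142 became 0.147 with DESeq2 size factors, 0.19 with spike-in scaling, 0.247 without a count filter, 0.114 at a mean count of at least 50, 0.167 in the kallisto-format table and 0.136 with the posterior filter. The coefficient of variation of 0.1004 became 0.0954 at a mean count of at least 50, 0.107 as the median trended value and 0.0863 with the posterior filter. The replicate correlation became 0.958 with a pseudocount of 0.1, 0.993 without a filter and 0.987 in the kallisto-format table, and that of the transcript tables became 0.771 with a pseudocount of 0.1. The spike-in SD of 0.15 became 0.253 at a mean count of at least 10 and 0.0841 at 500, where counting alone gives 0.27 and 0.0428. Of 44 lists, 22 lay outside their random range and 14 without matching on expression. The cause was not tested for these moves.

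Of the list medians under alternatives, 240 kept their side of the range, 12 left the outside, 4 came to lie outside (microglia in the kallisto-format table and with the posterior filter, presynaptic and heat shock genes in the kallisto-format table) and 2 reversed with spike-in scaling: list replicate difference, AMPA receptor subunits (0.011) and list replicate difference, imprinted genes (0.0443). Those that left it were CA2, CA3, AMPA receptors, immediate early genes, cholesterol synthesis, extracellular matrix, imprinted and ribosomal RNA-related genes without matching, and CA2, endothelial cells, AMPA receptors and imprinted genes in the kallisto-format table. Ependymal, choroid plexus and interferon lists gave no value at a mean count of at least 50, the first and last none with the posterior filter, and structural RNAs none in the kallisto-format table. Of the ratios of single genes, 633 kept their call, 24 fell short of the test, 4 newly passed it and 8 reversed: with spike-in scaling the log2 ratio of Rn7sk (0.0822), log2 ratio of Rn7s1 (0.0293), log2 ratio of Rn7s2 (0.0293) and log2 ratio of Gria3 (0.0315), and in the kallisto-format table the log2 ratio of Gm10925 (0.209), log2 ratio of Hist1h2ah (1.21), log2 ratio of Fam220a (0.0285) and log2 ratio of mt-Co2 (0.262). The cause was not tested. With 2 libraries no call has a replicate check, and genes under a mean count of 10 were not compared.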

Other observations

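The tests of the scaling, of the receptor density and of both explanations for the short RNAs, and the singling out of Slc17a6, Sox10, Olig1 and Olig2, were chosen only after the result was seen. The remaining tests were written before their result was seen, but the patterns themselves came from the same data. No biological explanation was tested, because the design has 1 group, so a difference between the animals of the replicates, such as litter or maturity at the same labelled age, stays open for the patterns that compare the replicates. The short RNA pattern compares 2 tables of the same library, so animals cannot cause it.

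Myelin genes were lower in replicate 2 by a median log2 ratio of -1.05. A scaling between libraries moves all genes alike, and the 4 scalings differed too little to remove the list's difference. The highest of the myelin medians over 4 scalings was -0.942, with medians of all genes from 0.00284 to 0.111. Scaling is thus argued against only by the gap between the list and all genes, which each of the 4 kept. A length or GC bias as the whole cause is argued against too. The median after subtracting genes of like length and GC content was -1.03 (bootstrap 95% interval -1.21 to -0.905). The bootstrap interval resamples the genes of the list and carries no replicate error. A candidate explanation that stays open is more thalamic tissue or adjoining white matter in the dissection of replicate 1. Of a further list of 11 thalamic genes, written before the test, all 11 were higher in replicate 1, with a median of -0.89 at percentile 0 of matched random lists, the test for thalamic tissue, led in level by Calb2 (TPM 46.9 and 41.8), Adarb1 (46.0 and 37.2) and Rora (20.7 and 11.5), and with Shox2 at 88 and 1 counts (log2 ratio -6.00, counting interval -11.9 to -4.08). In replicate 2, 9 of the 11 still had a TPM of at least 1, which either expression outside the thalamus or some thalamic tissue in that library would give. None of the 11 is in another list used here. That does not make them specific to the thalamus, and expression of either thalamic list in oligodendrocytes or hippocampal neurons was not tested. No sort or gate is named in the labels that would remove such tissue.

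A further list of 20 genes of mature oligodendrocytes had a median log2 ratio of -0.71, with 16 of 19 tested members lower in replicate 2 and Car2, Evi2a and Hapln2 not past the test. Sox10 had -0.34, Olig1 -0.11 and Olig2 -0.06, the last not past the test, with no test of how these differ from the list. The thalamic transporter gene Slc17a6 had 1060 and 852 counts (log2 ratio -0.45, adjusted p 2.7e-10 by the exact binomial test), while its TPM was 13.1 and 13.3. The cause of that gap was not tested.

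TEC and sense intronic genes, and nuclear RNAs such as Malat1, were lower in replicate 2. Low counts as the cause are argued against, since the TEC median of -0.481 lay outside the -0.054 to -0.0012 of matched random lists of protein-coding genes. For genomic DNA in replicate 1, the summed counts of 1504 receptor genes of smell and taste had a log2 ratio of -0.38 (-0.52 to -0.23), which did not decide, but their density in replicate 1 was 1.18% of that of the median TEC gene (0.2 against 17.0 counts per kb), too low for DNA to carry the pattern. More unspliced precursor RNA in replicate 1 may contribute: TEC genes inside expressed protein-coding genes on the same strand had a median of -0.51 (1045 genes) against -0.31 elsewhere (311 genes), a difference of -0.205 (bootstrap 95% interval -0.27 to -0.12). That leaves open why TEC genes elsewhere were lower as well. The bootstrap interval resamples genes within 1 pair of libraries, and genes are not replicates, so it carries no replicate error.

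Short structural RNAs were nearly missing from the kallisto-format table. A fragment length that the quantifier assumes could be the cause: the ratio of counts in the 2 tables was 0 in the median for genes under 300 nt and at least 0.97 for those over 1000 nt, and for long transcripts the length minus the effective length was 99 nt in the RSEM-format table and 346 nt in the kallisto-format table. Identical copies that share reads are argued against under 300 nt, since the ratio was also 0 in the 14 such genes with a posterior standard deviation of 0 in both libraries, a limit set after one of 5% (34 genes, ratio 0) proved to let near-identical copies through. From 300 to 500 nt the ratio was 0.298 in 10 such genes against 0.00666 in all 125, so shared reads may contribute there.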
